A study of Arabidopsis thaliana with 12 samples.

How the data were processed

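RNA from whole Arabidopsis thaliana seedlings was sequenced in 12 libraries, 3 for each combination of genotype (wild type or snap33) and age (5 d or 12 d). Per the labels' protocols, untreated seedlings were grown on solid medium under long days, and polyadenylated RNA was made into stranded single-read libraries. The protocol text of snap33 12 d replicate 1 also names a 3' sequencing format that the other 11 libraries do not carry. Per the submitters' processing notes, the authors aligned the reads with STAR (version not given) to the TAIR10 genome, and the closing lines of the deposited files are those written by htseq-count. The gene annotation, the counting settings and whether strand was used are not given in the sources used here. The deposited values are counts, whole numbers of reads per gene, with no normalization by the authors.

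Groups were taken from the sample titles. The genotype field of all 6 wild-type libraries also carries the word for a knock-out, and at 5 d the full description of the mutant, so the SNAP33 counts of every library are given first. Per the labels, snap33 plants of 12 d were planted on 9 March and harvested 32 to 34 days later, whereas all other plants were planted on 29 March and harvested 5 to 7 or 12 to 14 days later. The groups are named by the ages in their titles. The series design calls the libraries of a group biological replicates, but each group has 1 planting date and nothing says that its replicates came from separate plates or batches of seed, so p-values measure only the spread between these samples. Replicates of a group differed by more than sampling noise in every pair (chi-square per degree of freedom 1.59 to 9.98), so no library was treated as deposited more than once.

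The files held 32744 genes, of which 32548 matched the TAIR10.1 reference annotation by locus code; the 196 others were all organelle genes. TAIR10.1 was used for names and for the position of SNAP33, not for counting. The lines for reads not assigned to a gene (9.26% to 12.15% of the total per library) were left out of library sizes and tests. Gene counts came to 4304441 to 5754570 per library. Intervals on ratios of counts are exact at 95% and, like the floors, cover counting error only. A gene with 0 counts over a group is given as at least a fold against a floor of 3 counts over the group, and a gene with 1 to 3 counts as a ratio of counts with its interval. Counts cannot be divided with certainty between near-identical genes (for example the PDF1 defensins, CYP71A12 and CYP71A13, or the RBCS genes) or between overlapping genes, and 24 of the 111 genes named with values overlap another annotated gene. Other members of 1 gene family that were called in opposite directions, such as GSTF6 and GSTF7 or CYP79F1 and CYP79F2, were not checked for this. For CYP71A13 and CYP712A1 the overlap with an antisense gene spans 572 and 1775 bases, and FER4 and FBA5 overlap a neighbour on the same strand by 118 and 109 bases.

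Genes were tested with edgeR 4.0.16 in R 4.3.3, with the quasi-likelihood test on the deposited counts, TMM scaling, the default low-count filter (18830 genes kept) and Benjamini-Hochberg adjustment, and were called at an adjusted p under 0.05. All 12 libraries entered 1 fit with a mean per group, so that the 4 groups shared an estimate of the spread. The contrasts tested were snap33 against wild type at 5 d and at 12 d, the difference between those effects, and 12 d against 5 d within each genotype. CPM are counts scaled to library size with the TMM factors, given as mean ± SD over 3 libraries, and fold changes are log2 with an approximate SE. That SE is the absolute log2 fold change divided by the square root of the F statistic of the test. For genes near 0 counts it can lie below counting error, so it is no measure of their precision. Gene lists, 25 with 533 members, were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) at a preset correlation of 0.01, adjusted over the lists of a contrast, and again with the correlation estimated from the data. The second test also lost calls of lists with an estimate under the preset (0.009 for salicylic acid and 0.001 for hypoxia at 5 d). A loss alone therefore does not show that the members of a list are correlated.

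Groups, tests, gene lists, the rule for named genes and the alternative settings below were fixed before the data were examined. The rule named SNAP33 and 12 further genes of secretion and salicylic acid defence; the 6 genes with the largest fitted fold in each direction at each age among called genes with no overlap between the groups and at least 5 CPM in the higher group; up to 3 called members, by smallest p, of each list with a camera call or at least 3 called members; the 4 genes with the smallest p in each direction of the difference; and the 4 with the largest fitted fold in each direction with time. Genes given by symbol alone because they make up a list count of 5 or fewer were chosen after their values were seen.

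The alternative settings were median-ratio and upper-quartile scaling, DESeq2 1.42.0, no filter or a stricter filter on low counts (1 CPM in 6 libraries), only the groups compared, no organelle genes, no 20 most abundant genes, a fold of at least 2, each library left out in turn, fry for lists, and a replicate block. The fold of at least 2 was applied only to counts of genes, so ranges over all alternatives for single genes or lists leave it out. The numbers pair the samples, since within an age the labels give same-numbered libraries of both genotypes 1 harvest date. The correlation of their deviations from the group means over 12042 genes was -0.115, -0.439 and -0.168 at 5 d and -0.052, -0.156 and -0.023 at 12 d. For libraries of different numbers it ranged from -0.261 to 0.349 at 5 d and from -0.076 to 0.14 at 12 d. Same-numbered libraries were thus not more alike. Lists under other scalings and libraries thinned to 4304441 counts were added after the data were seen.

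The procedure was tested on simulated data, 18830 genes with 100 changed at log2 1 and 100 at log2 2. For 5 d edgeR recovered 77% and 96% of them, for 12 d 80% and 97%, for the difference 50% and 94%, for wild type over time 79% and 96%, and for snap33 over time 76% and 98%. False calls were 4.9% to 8.8% of calls. The changed genes had a mean of at least 2 CPM and were a far smaller share of genes than was called in the data. These rates therefore do not carry over to genes near 0 counts or to changes as wide as those called. A simulated shift of the photosynthesis list by -0.5 at 12 d was called by camera with either correlation and by fry, with 0 other lists called. Simulated genes were drawn independently, whereas the photosynthesis genes of the data had an estimated correlation of 0.514. The simulation therefore does not show how lists with correlated members fare.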

Results

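Gene expression was measured by RNA sequencing in whole Arabidopsis thaliana seedlings of 2 genotypes at 2 ages, to compare a snap33 mutant with wild type and to follow both over time. SNAP33 (AT5G61210) encodes a t-SNARE of the plasma membrane that acts with syntaxins in vesicle fusion and cell plate formation, and the labels describe the mutant as a T-DNA knock-out. Each of the 4 groups held 3 libraries. Gene counts summed to 4551031, 5330351 and 4601725 in wild-type replicates 1 to 3 at 5 d and to 4813508, 4304441 and 4489276 in snap33 at 5 d. At 12 d they summed to 4868244, 5754570 and 4834021 in wild type and to 5103854, 5383949 and 5028343 in snap33. Chloroplast-encoded genes took 3.97% of the counts in wild-type 12 d replicate 3 and 2.33% to 3.47% in the other libraries.

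**Figure D1:**
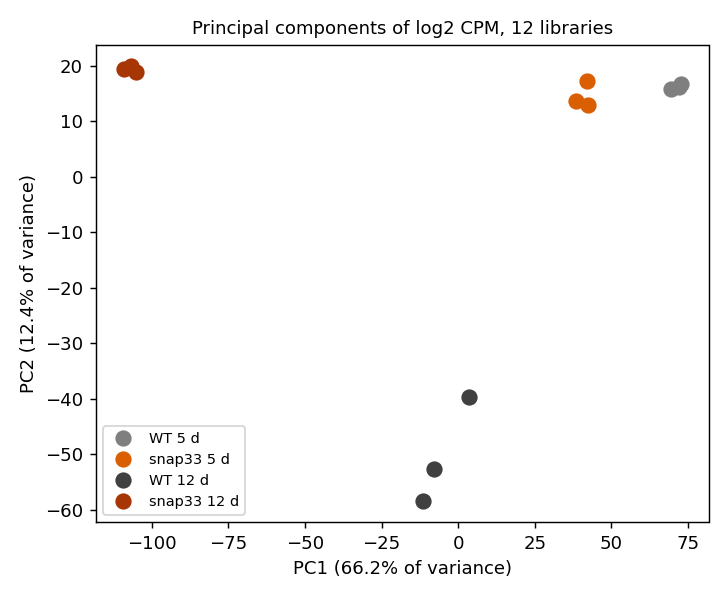
Principal components of log2 CPM of the 12 libraries, 1 point per library, with PC1 (66.2% of variance) on the x axis and PC2 (12.4%) on the y axis. The snap33 12 d libraries lie at 1 end of PC1, and the wild-type 12 d libraries stand apart from the other groups on PC2.

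SNAP33 was low in every snap33 library. Its raw counts were 95, 109 and 95 in wild-type replicates 1 to 3 and 1, 3 and 8 in snap33 at 5 d, and 119, 168 and 108 in wild type and 16, 14 and 14 in snap33 at 12 d. In CPM this was 0.95 ± 0.87 in snap33 against 21.3 ± 0.09 in wild type at 5 d (SD, n = 3), a 22.3-fold lower level (log2 fold change -4.48, SE 0.31, edgeR adjusted p = 9.65e-09). At 12 d it was 2.74 ± 0.19 against 24.4 ± 3.31 CPM, 8.85-fold lower (-3.15, SE 0.23, edgeR adjusted p = 1.78e-09). The gene lies on chromosome 5 at 24623248 to 24625631 on the + strand of TAIR10.1, with 2 transcripts of 5 exons each. Its ends overlap antisense genes by 59 and 257 bases, and counts per gene do not show where along the gene the remaining reads of the mutant fell.

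At 5 d the comparison asked which genes differ between snap33 and wild type in young seedlings. The jasmonate and ethylene response list moved most, with 29 of 35 tested members higher in snap33, 0 lower and 6 not called (median log2 fold change 2.07). PDF1.3 (AT2G26010), a plant defensin, stood at 199.8 ± 92.7 CPM in snap33 and 1.0 ± 0.56 in wild type (7.61, SE 0.41, edgeR adjusted p = 2.98e-10, n = 3). PDF1.2a (AT5G44420), another defensin, stood at 123 ± 58.7 against 0.49 ± 0.24 CPM (7.88, SE 0.47), and AOC1 (AT3G25760), an allene oxide cyclase of jasmonate synthesis, was 11.6-fold higher (79.3 ± 19.3 against 6.84 ± 1.06 CPM). LOX4 (AT1G72520), a lipoxygenase of the same pathway, was 4.77-fold higher (2.25, SE 0.2). Adjusted over the list alone, 30 members were higher and 1 lower, and the list was called by camera (adjusted p = 3.4e-31, and adjusted p = 0.0443 with an estimated correlation). In all, 2445 genes were called at 5 d, 1547 higher and 898 lower, of which 706 (574 higher and 132 lower) changed at least 2-fold. With upper-quartile scaling 1381 were higher and 1195 lower (53.6% against 63.3% higher). Of the called genes 98% had no overlap between the 3 libraries of each genotype, against 32% of all tested genes and 10% by chance. Calling selects such genes from the same values, so the share among called genes is no separate evidence, here or in the comparisons below. The count was 1515 without snap33 5 d replicate 3, 1468 (1018 of them higher) without wild-type 5 d replicate 2 and 1599 without wild-type 5 d replicate 3. Genes lower at 5 d numbered 489 with the replicate block, 466 and 403 without snap33 5 d replicate 1 or 3, and 586, 450 and 480 without wild-type 5 d replicate 1, 2 or 3.

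Several genes higher in snap33 at 5 d were at or near 0 counts in wild type. CSLA01 (AT4G16590), a cellulose synthase-like gene, had 834 counts over the 3 snap33 libraries and 1 over the wild-type libraries, a 908-fold ratio with a counting interval of 163 to 35900. PDF1.2c (AT5G44430) had 702 against 2 counts (382-fold, interval 105 to 3160). FAMT (AT3G44860), a farnesoic acid methyltransferase, TAT3 (AT2G24850), a tyrosine aminotransferase, and THI2.1 (AT1G72260), a thionin, had 0 counts in wild type and were at least 74.1-fold, 49-fold and 31.9-fold higher. The call of TAT3 was lost without snap33 5 d replicate 1 (edgeR adjusted p = 0.0618, against 3.31e-07 to 0.0618 over all alternatives). MBP1 (AT1G52040), a myrosinase-binding protein, stood at 117 ± 37.6 against 0.36 ± 0.27 CPM (8.27, SE 0.37). Among the genes lower in snap33, GASA5 (AT3G02885), a gibberellin-regulated peptide gene, was 13.6-fold lower (1.86 ± 0.61 against 25.7 ± 9.39 CPM), and AT5G14650, a pectin lyase-like gene, had 3 against 71 counts (21.7-fold lower, interval 7.14 to 108). AT2G47880, a glutaredoxin, AT4G08780, a peroxidase, and FTM1 (AT1G43800), a fatty acid desaturase, were 5.26-fold, 3.81-fold and 3.7-fold lower.

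Defence groups other than jasmonate were partly higher at 5 d. In the salicylic acid list 6 of 27 members were higher, 1 (WRKY54) lower and 20 not called, the same numbers when adjusted over the list alone (median 0.23, or 0.21 with members at 0 counts set to their bound). SARD1 (AT1G73805), a transcription factor that activates salicylic acid synthesis, was 4.23-fold higher (2.08, SE 0.41), PBS3 (AT5G13320), an enzyme of that synthesis, 6.15-fold, and DMR6 (AT5G24530), a salicylic acid hydroxylase, 1.7-fold higher. ICS1 (AT1G74710), the isochorismate synthase of the pathway, stood at 14.3 ± 1.96 against 9.42 ± 0.96 CPM (0.6, SE 0.17, edgeR adjusted p = 0.0268). That call was lost with the replicate block (edgeR adjusted p = 0.072), and without snap33 5 d replicate 2 (0.107), wild-type 5 d replicate 2 (0.106) or wild-type 5 d replicate 3 (0.0797), within a range of 0.0168 to 0.107 over all alternatives, thinning (0.0604) included. EDS1 (AT3G48090) and PAD4 (AT3G52430), lipase-like regulators of immunity, and NPR1 (AT1G64280), a salicylic acid receptor, were not called, with log2 fold changes of 0.23 (SE 0.19), 0.22 (SE 0.18) and 0.21 (SE 0.17). The list was called by camera (adjusted p = 0.00404, but adjusted p = 0.0642 with an estimated correlation). Its estimated correlation was 0.009, under the preset 0.01, so a higher correlation among its members does not explain that loss.

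Of the 12 pathogenesis-related and systemic resistance markers, 5 were higher (PR2, AED1, PNP-A, PCC1 and BCB), 0 lower and 7 not called, with 8 higher adjusted over the list alone (median 1.54). PR2 (AT3G57260), a glucanase, stood at 14.0 ± 10.4 against 1.07 ± 0.24 CPM (3.7, SE 0.65), AED1 (AT5G10760), a secreted protease, was 44.6-fold higher (5.48, SE 0.49), and PNP-A (AT2G18660), a natriuretic peptide, had 56 against 3 counts (20.3-fold, interval 6.61 to 102). PR5 (AT1G75040), a thaumatin-like protein, was not called (-0.32, SE 0.28), nor was PR1 (AT2G14610), a marker of salicylic acid defence, with a mean of 0.23 CPM in snap33 and 0.07 in wild type. Camera called the markers (adjusted p = 4.41e-05, but adjusted p = 0.124 with an estimated correlation). Of the 33 immune receptors and receptor kinases 11 were higher, 1 (WAK2) lower and 21 not called, 13 and 1 adjusted over the list alone (median 0.48, or 0.4 at the bounds). RLP23 (AT2G32680), a receptor-like protein that binds a microbial peptide, was 11.9-fold higher, and CRK6 (AT4G23140), a cysteine-rich receptor kinase, had 45 against 2 counts (24.5-fold, interval 6.4 to 209). Of 21 defence WRKY factors 7 were higher, 0 lower and 14 not called, the same adjusted over the list alone (median 0.47), with WRKY46 (AT2G46400) 5.94-fold and WRKY45 (AT3G01970) 3.09-fold higher. Camera called both lists (adjusted p = 1.84e-05 and 0.000319), also with an estimated correlation (adjusted p = 0.0178 and 0.0426), and at 5 d only these lists and the jasmonate list were called both ways.

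Part of the flavonoid, abscisic acid and senescence genes were higher at 5 d as well. The flavonoid and anthocyanin list had 11 of 16 members higher, 0 lower and 5 not called, the same adjusted over the list alone (median 1.03), and TT7 (AT5G07990), a flavonoid hydroxylase, and PAP1 (AT1G56650), a MYB activator of anthocyanin genes, were 2.85-fold and 2.39-fold higher. The abscisic acid, cold and dehydration list had 12 of 20 higher, 0 lower and 8 not called, 13 and 1 adjusted over the list alone (median 0.91), with RD20 (AT2G33380), a caleosin, 11.1-fold and COR15A (AT2G42540), a cold-induced chloroplast protein, 7.16-fold higher. The senescence and chlorophyll breakdown list had 7 of 22 higher, 0 lower and 15 not called, 12 higher adjusted over the list alone (median 0.65), with SEN1 (AT4G35770), a dark-induced gene, 8.77-fold and DIN6 (AT3G47340), an asparagine synthetase, 5.52-fold higher. Camera called the 3 lists (adjusted p = 3.97e-08, 1.35e-07 and 1.97e-06), but not with an estimated correlation (adjusted p = 0.0556, 0.124 and 0.124). In the camalexin and indole glucosinolate list 5 of 17 members were higher (CYP79B2, CYP79B3, CYP83B1, GSTF6 and GGP1), 2 lower (GSTF7 and CYP81F2) and 10 not called, 7 and 2 adjusted over the list alone (median 0.33). CYP79B3 (AT2G22330), which converts tryptophan to indole acetaldoxime, was 2.41-fold higher. That list's camera call (adjusted p = 0.0314) was lost with an estimated correlation (adjusted p = 0.241). It was also lost without snap33 5 d replicate 1 or 2 or wild-type 5 d replicate 1 (camera adjusted p = 0.0647, 0.0704 and 0.0963, in a range of 0.00656 to 0.241 over all alternatives).

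Part of the cell division genes and of the root hair markers were lower at 5 d. In the cell division and cytokinesis list 0 of 38 members were higher, 7 lower and 31 not called, 8 lower adjusted over the list alone (median -0.31), and PCNA1 (AT1G07370), the sliding clamp of DNA replication, was 1.88-fold lower (21.7 ± 3.21 against 40.8 ± 0.81 CPM). KNOLLE (AT1G08560), the cytokinesis syntaxin that pairs with SNAP33, was not called (0.08, SE 0.16). Of 9 root hair markers 5 were lower (EXPA18, COBL9, LRX1, PRP1 and PRP3), 0 higher and 4 not called, 7 lower adjusted over the list alone (median -0.93). PRP1 (AT1G54970), a proline-rich wall protein of root hairs, was 2.39-fold lower (-1.26, SE 0.34, edgeR adjusted p = 0.0176). Its call was lost without snap33 5 d replicate 1 (0.0623), snap33 5 d replicate 3 (0.0637) or wild-type 5 d replicate 2 (edgeR adjusted p = 0.131, range over all alternatives 0.005 to 0.131). That of LRX1 (AT1G12040), a root hair wall protein, was lost with DESeq2 (adjusted p = 0.0677) and without snap33 5 d replicate 1 (0.0503) or 3 (0.084) or wild-type 5 d replicate 2 (0.0726), in a range of 0.0119 to 0.084. That of PRP3 (AT3G62680) was lost without snap33 5 d replicate 1 (edgeR adjusted p = 0.103) or wild-type 5 d replicate 2 (0.0909) or 3 (0.0761), in a range of 0.00114 to 0.103. Those of EXPA18 (AT1G62980) and COBL9 (AT5G49270) were lost under 5 and 10 of 22 alternatives (edgeR adjusted p up to 0.152 and 0.179). Camera called both lists (adjusted p = 0.000407 and 4.86e-05), but not with an estimated correlation (adjusted p = 0.241 for both).

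Photosynthesis, hypoxia and phosphate starvation genes were called as lists at 5 d with few called members. Photosynthesis had 0 of 50 members called, also adjusted over the list alone, around a median of 0.13 (camera adjusted p = 0.0407, and adjusted p = 0.696 with an estimated correlation). That call was lost with the replicate block (camera adjusted p = 0.0916), with fry (0.324), with upper-quartile scaling (0.0959) and without the 20 most abundant genes (0.0642). It was also lost without snap33 5 d replicate 1 (camera adjusted p = 0.389) or 3 (0.289) and without wild-type 5 d replicate 1 (0.235) or 3 (0.282), in a range of 0.000101 to 0.696. Of 11 hypoxia response genes 1 was higher (HUP26, a hypoxia-induced gene, 2.77-fold), 1 lower (LBD41) and 9 not called, 1 and 5 adjusted over the list alone (median -0.48, camera adjusted p = 0.0361, and adjusted p = 0.124 with an estimated correlation). The hypoxia call was lost without snap33 5 d replicate 1 or 3 or wild-type 5 d replicate 1 (camera adjusted p = 0.0761, 0.0592 and 0.0963) and with upper-quartile scaling (0.0532), in a range of 0.0133 to 0.124. Of 9 phosphate starvation genes 1 was higher (PAP17, an acid phosphatase, 1.9-fold), 0 lower and 8 not called, the same adjusted over the list alone (median 0.46). Camera called that list (adjusted p = 0.0173, and adjusted p = 0.528 with an estimated correlation), and fry did not (adjusted p = 0.12, in a range of 0.00107 to 0.528).

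At 12 d the comparison asked the same question in older seedlings, and salicylic acid defence genes were higher in snap33. Of 27 salicylic acid genes 25 were higher, 0 lower and 2 not called, the same adjusted over the list alone (median 3.39, camera adjusted p = 5.92e-20). ICS1 stood at 148 ± 7.89 CPM in snap33 and 14.0 ± 2.41 in wild type (3.39, SE 0.14, edgeR adjusted p = 2.3e-13, n = 3). PAD4 was 14.2-fold, EDS1 4.3-fold, NPR1 2.07-fold and PBS3 29.1-fold higher, and WRKY70 (AT3G56400), a factor of salicylic acid signalling, 22.1-fold (476 ± 3.92 against 21.5 ± 1.63 CPM). All 12 pathogenesis-related and systemic resistance markers were higher, also adjusted over the list alone (median 4.64, camera adjusted p = 6.39e-11). PR1 stood at 1362 ± 107 against 9.08 ± 4.07 CPM, 147-fold higher (7.2, SE 0.22, edgeR adjusted p = 1.3e-14), PR2 was 27.5-fold and PR5 16.5-fold higher, and PCR1 (AT1G14880), a cadmium resistance protein, 43-fold higher. In all, 7826 genes were called at 12 d, 3964 higher and 3862 lower, of which 2590 (1770 higher and 820 lower) changed at least 2-fold. With upper-quartile scaling 3199 were higher and 5186 lower (38.2% against 50.7% higher), as that scaling moved the median of all genes from -0.037 to -0.156. Of the called genes 95.4% had no overlap between the genotypes, against 50.2% of all tested genes and 10% by chance. The snap33 plants of this comparison carry an earlier planting date than wild type in the labels (32 to 34 against 12 to 14 days before harvest), which no fit can separate from genotype.

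**Figure D2:**
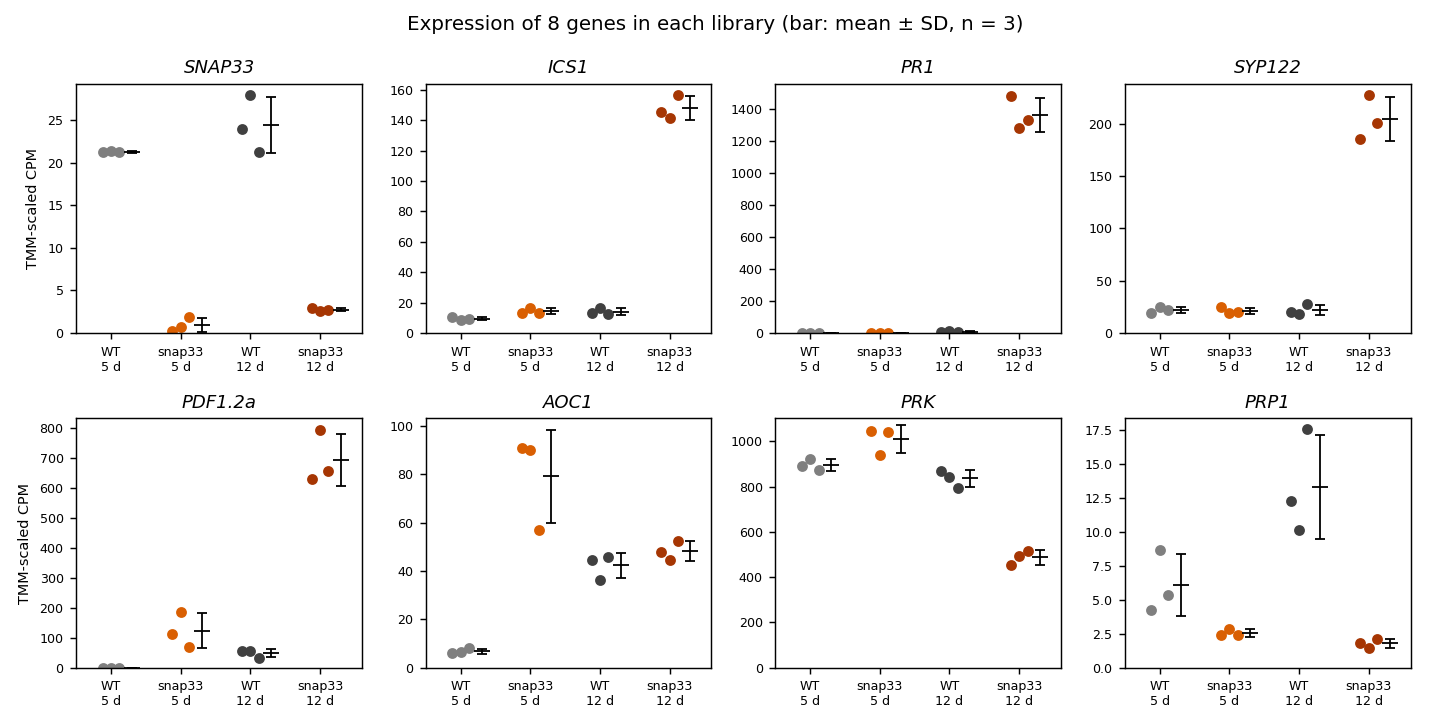
TMM-scaled CPM (y axes, linear from 0) of 8 genes in each of the 12 libraries by genotype and age (x axes), 1 point per library, with bars for the mean and SD of 3 libraries. SNAP33 is low in both snap33 groups, PR1, ICS1 and SYP122 are high in snap33 at 12 d, and AOC1 is highest in snap33 at 5 d (79.3 ± 19.3 CPM).

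Other branches of immunity and part of the oxidative stress genes were higher at 12 d too. Of 33 immune receptors and receptor kinases 30 were higher, 0 lower and 3 not called, 31 higher adjusted over the list alone (median 1.66), among them SOBIR1 (AT2G31880), a co-receptor of receptor-like proteins (5.68-fold), WAKL10 (AT1G79680), a wall-associated kinase-like protein (21.7-fold), and CRK36 (AT4G04490), a cysteine-rich receptor kinase (68.1-fold). Of 21 defence WRKY factors 20 were higher, 0 lower and 1 not called, the same adjusted over the list alone (median 2.24), with WRKY51 (AT5G64810) 48.8-fold and WRKY46 14.9-fold higher. In the camalexin and indole glucosinolate list 16 of 17 were higher and 1 (MYB34) lower, the same adjusted over the list alone (median 1.82). CYP71A13 (AT2G30770) and CYP71A12 (AT2G30750), near-identical cytochromes of camalexin synthesis, were 77.7-fold and 25.4-fold higher, and PAD3 (AT3G26830), which forms camalexin, 17.7-fold (208 ± 10.4 against 11.5 ± 5.16 CPM). Of 31 oxidative stress and detoxification genes 18 were higher, 2 (UPOX and CAT2) lower and 11 not called, the same adjusted over the list alone (median 1.08), with AOX1D (AT1G32350), an alternative oxidase, 24.9-fold and ZAT12 (AT5G59820), a zinc finger factor, 7.69-fold higher. Camera called these 4 lists (adjusted p = 3.01e-17, 1.09e-13, 7.68e-09 and 7.23e-08). These 4, the salicylic acid list, the systemic resistance markers and the endoplasmic reticulum list were also called with an estimated correlation at 12 d, by camera at adjusted p = 0.000144 to 0.023.

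The jasmonate and ethylene list had 27 of 35 members higher, 1 (JAZ9) lower and 7 not called at 12 d, the same adjusted over the list alone (median 1.18, camera adjusted p = 6.44e-10, but adjusted p = 0.19 with an estimated correlation). PDF1.2a was 14.3-fold higher (695 ± 86.8 against 48.4 ± 13.6 CPM) and LOX4 7.48-fold, while AOC1 was not called (0.19, SE 0.16). The senescence list had 14 of 22 higher, 2 (SAG29 and RNS1) lower and 6 not called, the same adjusted over the list alone (median 0.88). JUB1 (AT2G43000) and ANAC055 (AT3G15500), NAC factors, were 17.3-fold and 7.61-fold higher. Flavonoid and anthocyanin genes had 10 of 16 higher, 1 (CHS) lower and 5 not called, 10 and 3 adjusted over the list alone (median 1.31), with LDOX (AT4G22880), an anthocyanin synthase, 3.63-fold and PAP1 3.12-fold higher. Camera called both lists (adjusted p = 0.000496 and 0.00177), but not with an estimated correlation (adjusted p = 0.232 and 0.195).

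Endoplasmic reticulum genes and part of the SNARE and exocyst genes were higher at 12 d. In the endoplasmic reticulum folding and unfolded protein response list 18 of 21 were higher, 0 lower and 3 not called, the same adjusted over the list alone (median 0.64, camera adjusted p = 1.13e-07). BIP3 (AT1G09080), a chaperone, was 9.88-fold, CRT3 (AT1G08450), a calreticulin, 3.03-fold and bZIP60 (AT1G42990), a factor of the unfolded protein response, 2.74-fold higher. In the SNARE and exocyst list 13 of 33 were higher, 2 (NPSN12 and SEC5A) lower and 18 not called, 13 and 3 adjusted over the list alone (median 0.37, camera adjusted p = 0.0062, but adjusted p = 0.117 with an estimated correlation). SYP122 (AT3G52400), a plasma membrane syntaxin, stood at 205 ± 21.4 against 21.9 ± 4.83 CPM (9.36-fold, log2 3.23, SE 0.15), and SYP121 (AT3G11820), the syntaxin of penetration resistance, was 2.57-fold higher. EXO70B2 (AT1G07000), an exocyst subunit, was 7.1-fold and VAMP722 (AT2G33120), a vesicle SNARE that pairs with SYP121, 2.64-fold higher. KNOLLE was not called (0.14, SE 0.18). SNAP29 (AT5G07880) and SNAP30 (AT1G13890), the other members of the SNAP33 family, were too low to be tested, with at most 0.32 CPM for SNAP29 in any group and 0 counts for SNAP30.

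Most photosynthesis, wall and root genes tested were lower at 12 d. Of 50 nuclear photosynthesis genes 0 were higher, 43 lower and 7 not called, 46 lower adjusted over the list alone (median -0.51, camera adjusted p = 1.3e-11, but adjusted p = 0.235 with an estimated correlation). PRK (AT1G32060), phosphoribulokinase, stood at 487 ± 31.6 against 836 ± 39.1 CPM (-0.78, SE 0.09), and RBCS2B (AT5G38420), a Rubisco small subunit, was 1.88-fold lower. Of 11 wall expansion and cellulose genes 7 were lower, 1 (PMR4) higher and 3 not called, 8 and 1 adjusted over the list alone (median -0.5), with XTH4 (AT2G06850), a xyloglucan endotransglucosylase, 2.8-fold and EXPA8 (AT2G40610), an expansin, 4.76-fold lower. All 9 root hair markers were lower, also adjusted over the list alone (median -1.48), PRP1 by 7.24-fold, and 7 of 9 root endodermis and other root markers were lower with 2 not called, the same adjusted over the list alone (median -0.9), CASP1 (AT2G36100), a Casparian strip protein, by 2-fold. Camera called these 3 lists (adjusted p = 0.00551, 1.41e-05 and 0.00332), but not with an estimated correlation (adjusted p = 0.166, 0.195 and 0.352).

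Several genes called at 12 d were at or near 0 counts in 1 genotype. AT5G46960, an invertase inhibitor-like gene, had 1045 counts over the snap33 libraries and 1 over wild type (1050-fold, interval 187 to 41300), AT2G44240 1899 against 3 (633-fold, 216 to 3070) and AT4G10860 1465 against 3 (489-fold, 167 to 2370). AT5G66890, a leucine-rich repeat gene, AT5G44990, a glutathione transferase, and AT5G64790, a glycosyl hydrolase, had 0 counts in wild type and were at least 66.7-fold, 65-fold and 58.7-fold higher. Among the genes lower in snap33, CYP712A1 (AT2G42250), a cytochrome, had 1 against 108 counts (108-fold lower, interval 19 to 4300), and PAP14 (AT2G46880), a purple acid phosphatase, 0 against 101 (at least 33.6-fold lower), although DESeq2 did not call PAP14 (adjusted p = 0.179, in a range of 6.62e-10 to 0.179 over all alternatives). IPS1 (AT3G09922), a noncoding RNA induced by phosphate starvation, was 33-fold lower (0.82 ± 0.5 against 27.8 ± 13.8 CPM), AT2G08820, a noncoding RNA, 29.5-fold and GH9B13 (AT4G02290), a glycosyl hydrolase, 10.4-fold lower.

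**Figure D3:**
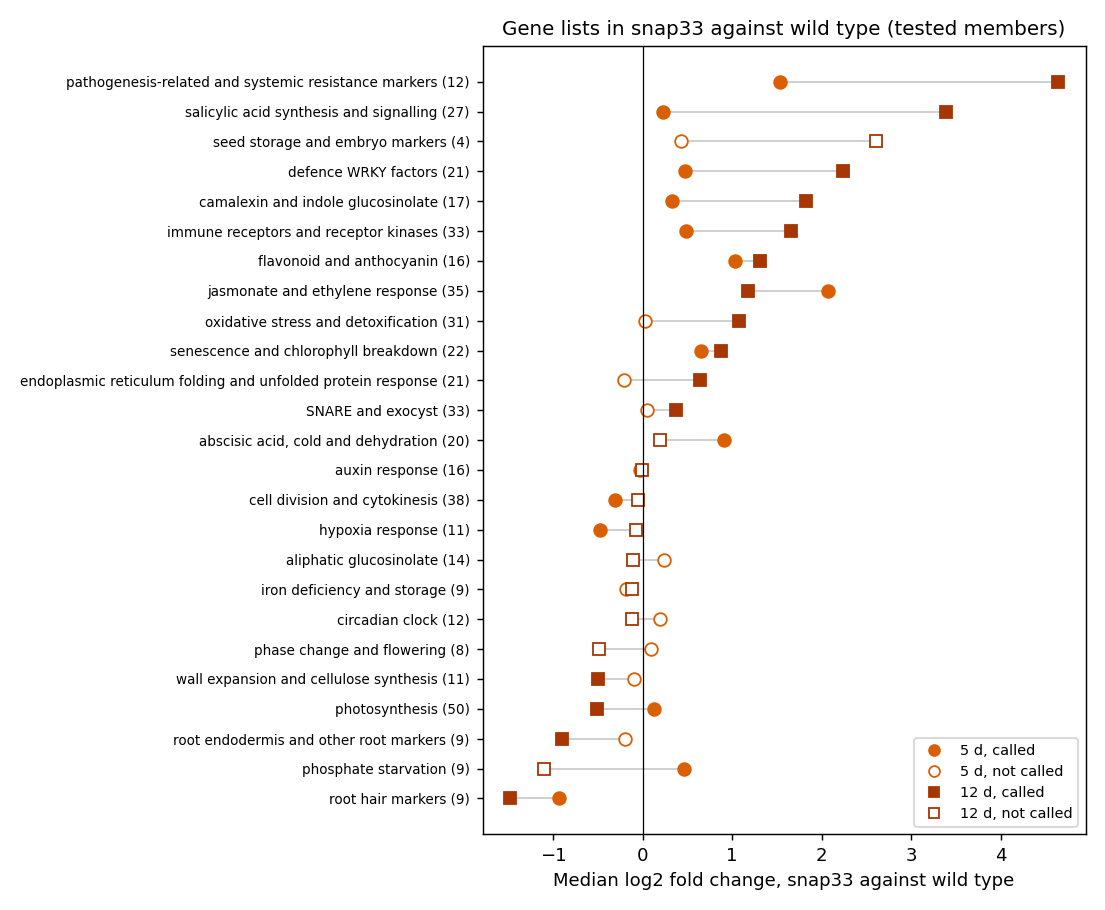
Median log2 fold change of snap33 against wild type (x axis) of the tested members of 25 gene lists (y axis, number tested in brackets) at 5 d (circles) and 12 d (squares). Filled symbols mark lists called by camera at a preset correlation, for example the salicylic acid list, with medians of 0.23 at 5 d and 3.39 at 12 d.

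Comparing the ages, 703 genes were higher in snap33 at both (325.7 for independent lists, odds ratio 3.58, Fisher's exact p = 1.17e-112) and 373 lower at both (184.2 for independent lists, odds ratio 2.94, Fisher's exact p = 7.27e-49). Genes called in opposite directions numbered 172 (higher at 5 d, 317.3 for independent lists) and 57 (lower at 5 d, 189 for independent lists). With upper-quartile scaling 576 were higher at both ages and 601 lower (48.9% against 65.3% higher), and without wild-type 5 d replicate 2 the shared calls came to 711. Genes lower at both ages numbered 197 with the replicate block, 208 and 187 without snap33 5 d replicate 1 or 3, 247 and 246 without snap33 12 d replicate 1 or 3, 198 and 195 without wild-type 5 d replicate 2 or 3, and 587 without wild-type 12 d replicate 3. The 5 d and 12 d comparisons share no library, but they share an estimate of the spread, and genes are not independent replicates. The p-values therefore only describe the overlap. With only the groups compared in each fit, 1047 genes were shared in direction, against 1076 in the main fit. Across all 18830 genes the log2 fold changes of the ages correlated at r = 0.341 (Pearson), and 59.3% had the same sign. For the 2445 genes called at 5 d these values were r = 0.571 and 72.8%.

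The log2 fold change of snap33 against wild type differed between the ages for 4466 genes, 2065 with a higher and 2401 with a lower value at 12 d than at 5 d. Higher and lower effects refer to the signed value, here and in the closer look below. A higher effect can thus be a smaller decrease, and a lower effect a larger decrease. With upper-quartile scaling 1738 were higher and 2919 lower (37.3% against 46.2% higher), and the planting date of snap33 at 12 d cannot be separated from genotype here either. In the salicylic acid list 18 of 27 members had a higher effect at 12 d, 0 a lower one and 9 were not called (20 higher adjusted over the list alone, median difference 2.79, camera adjusted p = 3.3e-21). The jasmonate list went the other way, with 18 of 35 lower, 7 higher and 10 not called, 20 and 8 adjusted over the list alone (median -1.17, camera adjusted p = 0.0035, but adjusted p = 0.471 with an estimated correlation). Among the genes with the smallest p, FLOT1 (AT5G25250), a flotillin of membrane microdomains, had a log2 difference of 5.07, GLP9 (AT4G14630), a germin-like protein, 5.54, YLS9 (AT2G35980), a defence-associated membrane protein, 5.71 and AT2G18690 3.64. FBA5 (AT4G26530), a fructose-bisphosphate aldolase, had -2.83, AOC1 -3.34, AT2G03980, a lipase-like gene, -2.15 and AT5G03545, a noncoding RNA of the IPS1 family, -3.27. Photosynthesis genes had 43 of 50 lower, 0 higher and 7 not called, 44 lower adjusted over the list alone (median -0.66, camera adjusted p = 1.57e-13, but adjusted p = 0.257 with an estimated correlation).

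In wild type, the time comparison asked what changed between 5 d and 12 d. Jasmonate and ethylene genes rose, with 33 of 35 higher at 12 d, 0 lower and 2 not called (33 higher adjusted over the list alone, median 2.14), PDF1.2a from 0.49 ± 0.24 to 48.4 ± 13.6 CPM and AOC1 from 6.84 ± 1.06 to 42.4 ± 5.13. Abscisic acid, cold and dehydration genes had 18 of 20 higher, 0 lower and 2 not called (20 higher adjusted over the list alone, median 1.94), with RD20 at a log2 fold change of 6.68 (SE 0.35). Senescence genes had 17 of 22 higher, 0 lower and 5 not called (19 adjusted over the list alone, median 1.3), and phase change and flowering genes 7 of 8 higher, 0 lower and 1 not called (8 adjusted over the list alone, median 2.15). Of 38 cell division genes 29 fell, 0 rose and 9 were not called (32 lower adjusted over the list alone, median -1.02), KNOLLE from 31.1 ± 2.17 to 13.1 ± 3.04 CPM, and of 16 flavonoid genes 15 fell, 0 rose and 1 was not called (the same adjusted over the list alone, median -1.19). Camera called these 6 lists (adjusted p = 6.32e-15, 8.3e-14, 2.4e-10, 0.000104, 1.96e-12 and 6.04e-11), of which the jasmonate list was lost with an estimated correlation (adjusted p = 0.0779).

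Part of the salicylic acid genes rose with time in wild type. Of 27 salicylic acid genes 12 rose, 1 fell and 14 were not called (the same adjusted over the list alone, median 0.47, camera adjusted p = 0.0028). ICS1 had a log2 fold change of 0.58 (SE 0.17, edgeR adjusted p = 0.0093), lost without wild-type 12 d replicate 2 (edgeR adjusted p = 0.0647, range 0.00506 to 0.0647 over all alternatives), and EDS1 was not called (-0.16, SE 0.19). PR1 went from 1 to 150 counts (131-fold, interval 23.2 to 5220). AT5G15500, an ankyrin repeat gene, FAMT and TAT3 had 0 counts at 5 d and were at least 176-fold, 125-fold and 61.8-fold higher at 12 d, and ANAC019 (AT1G52890), a NAC factor, had 655 against 1 count (573-fold, interval 103 to 22700). Large falls were in AT3G12900 (-5.34, SE 0.4), AT2G34700 (-4.49, SE 0.58), AT3G61400 (-4.02, SE 0.44) and AT5G40590 (-4.01, SE 0.36). In all, 7670 genes were called, 4055 higher and 3615 lower, 2489 of them by at least 2-fold, and 94.4% had no overlap between the ages, against 48.3% of all tested genes and 10% by chance. With upper-quartile scaling the larger share turned, with 3568 higher and 4145 lower (46.3% against 52.9% higher).

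In snap33, immune genes rose from 5 d to 12 d, though by the labels the 12 d plants were harvested 32 to 34 days after planting and the 5 d plants 5 to 7 (12 to 14 and 5 to 7 in wild type), so the time step may be longer than that of wild type. All 33 immune receptors and all 12 systemic resistance markers rose, also adjusted over each list alone (medians 2.1 and 4.59), and of 27 salicylic acid genes 25 rose, 1 fell and 1 was not called, the same adjusted over the list alone (median 3.37). ICS1 went from 14.3 ± 1.96 to 148 ± 7.89 CPM (3.37, SE 0.14), and PR1 from 3 to 21880 counts (5860-fold, interval 2010 to 28400). Camera called the 3 lists (adjusted p = 1.77e-14, 6.82e-09 and 3.47e-15), also with an estimated correlation (adjusted p = 0.000396, 0.0436 and 0.000396). Jasmonate genes had 21 of 35 higher, 3 lower and 11 not called, the same adjusted over the list alone (median 1.46, camera adjusted p = 0.000157, but adjusted p = 0.38 with an estimated correlation), and AOC1 fell from 79.3 ± 19.3 to 48.4 ± 3.96 CPM (-0.71, SE 0.16). Of 50 photosynthesis genes 47 fell, 0 rose and 3 were not called (48 lower adjusted over the list alone, median -0.78, camera adjusted p = 5.69e-13, but adjusted p = 0.185 with an estimated correlation), whereas in wild type 12 fell, 2 rose and 36 were not called (10 and 2 adjusted over the list alone, median -0.1, camera adjusted p = 0.0781). KNOLLE fell in snap33 too (-1.18, SE 0.17), and SNAP33 itself was higher at 12 d (1.53, SE 0.43, edgeR adjusted p = 0.00561). GSTU3 (AT2G29470), a glutathione transferase, AT5G63225 and AOX1D had 0 counts at 5 d and were at least 1040-fold, 647-fold and 598-fold higher at 12 d. Large falls were in AT3G12900 (-5.17, SE 0.44), AT2G08950 (-4.11, SE 0.63), ICL (AT3G21720), the isocitrate lyase of the glyoxylate cycle (-4.02, SE 0.33), and AT1G08757 (-3.93, SE 0.28). In all, 10315 genes were called, 5305 higher and 5010 lower, 4283 of them by at least 2-fold, and 96.9% had no overlap between the ages, against 63% of all tested genes and 10% by chance. With upper-quartile scaling 4371 were higher and 6313 lower (40.9% against 51.4% higher), as the median of all genes moved from 0 to -0.142.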

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

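The tests on induced genes and the count over all splits that part the pairs were chosen only after the result was seen. What stood out was the difference between the effects of snap33 at 12 d and at 5 d, tested in 1 fit over all 12 libraries, which was called for 4466 genes, 15 lists and 74 of the 111 genes named with values (edgeR adjusted p from 8.01e-10 to 0.0497 among these). The rule picked most named genes by their changes in these data, so their share cannot be read against the 23.7% of all tested genes called. Groups of 3 libraries were not tested for outlying libraries. Wild-type 12 d replicate 3 differed more from replicates 1 and 2 (chi-square per degree of freedom 7.58 and 9.98) than those did from each other (3.97), and without it 3223 genes were called at 5 d, a comparison that does not include it but shares the estimate of the spread. Of these 74 calls 64 held under every library left out and every other setting run on single genes, and 10 were lost under at least 1. A fold of at least 2 was not among those settings. Some of the 64 lie under it, such as PRK (log2 difference -0.95) and CYP79B3 (-0.69).

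The immune lists had higher signed effects at 12 d, with median log2 differences of 2.79 for salicylic acid, 2.18 for systemic resistance markers, 0.97 for immune receptors, 1.32 for WRKY factors and 1.08 for camalexin and indole glucosinolates. So did the lists of oxidative stress (0.75) and endoplasmic reticulum folding (0.93). The SNARE and exocyst list had 0.18 (camera adjusted p = 0.0408). Lower signed effects at 12 d, which can mean a smaller increase, a larger decrease or a change of direction, were seen for jasmonate (-1.17), photosynthesis (-0.66), wall expansion (-0.59), abscisic acid and cold (-0.61), phosphate starvation (-1.55), root hair (-0.76) and endodermis and other root markers (-0.8). With an estimated correlation 6 of the 15 were called, namely salicylic acid, immune receptors, WRKY factors, camalexin, oxidative stress and endoplasmic reticulum folding. The SNARE call was lost with the replicate block (camera adjusted p = 0.051) and without snap33 12 d replicate 1 (0.0536), snap33 5 d replicate 1 (0.0583), wild-type 12 d replicate 1 (0.0556) or 2 (0.0837), or wild-type 5 d replicate 1 (0.061) or 3 (0.0671), in a range of 0.000914 to 0.257. The root hair call was lost without snap33 5 d replicate 2 (camera adjusted p = 0.0991), wild-type 12 d replicate 3 (0.153) or wild-type 5 d replicate 1 (0.116) and with fry (0.0936), in a range of 0.00317 to 0.469. The endodermis call was lost without wild-type 12 d replicate 3 (camera adjusted p = 0.0779) and with fry (0.0702), in a range of 0.00138 to 0.462.

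The differences of genes are signed too. GASA5 (log2 fold change -3.76 at 5 d and -1.54 at 12 d) counts as higher, though its decrease was smaller at 12 d. PRP1 (-1.26 and -2.86) counts as lower, though its decrease was larger. Among secretion and salicylic acid genes the log2 differences were 1.33 for SNAP33, 1.2 for SYP121, 3.27 for SYP122, 2.56 for EXO70B2, 1.41 for VAMP722, 2.79 for ICS1, 1.88 for EDS1, 3.61 for PAD4, 0.84 for NPR1, 4.36 for PR5, 1.37 for DMR6, 3.13 for SARD1, 3.61 for WRKY70, 1.33 for WRKY46, 5.64 for WRKY51, 4.67 for PCR1 and 1.96 for SOBIR1. Other genes with higher effects at 12 d were CYP71A12 (4.54), PAD3 (3.84), JUB1 (4.22), ANAC055 (1.97), ZAT12 (2.32), BIP3 (1.88), CRT3 (1.4), bZIP60 (1.25), ERDJ3B (AT3G62600), a chaperone partner (1.6), LDOX (0.74), BHLH38 (AT3G56970), an iron deficiency factor (1.92), TOC1 (AT5G61380), an evening clock gene (1.14), PCNA1 (0.71), GASA5 (2.22), AT2G47880 (1.98), AT4G08780 (3.82), AT3G61400 (4.93), FLOT1 (5.07), GLP9 (5.54), YLS9 (5.71) and AT2G18690 (3.64). Lower effects were found for MBP1 (-3.58), PDF1.3 (-4.76), PDF1.2a (-4.04), AOC1 (-3.34), CYP79B3 (-0.69), SEN1 (-3.35), DIN6 (-1.88), RD20 (-3.15), COR15A (-2.4), PRP1 (-1.6), HUP26 (AT3G10020) (-0.97), PAP17 (AT3G17790) (-1.07), AT2G08820 (-5.37), GH9B13 (-2.75), PRK (-0.95), RBCS2B (-0.78), XTH4 (-1.22), EXPA8 (-2.12), CASP1 (-0.8), SQD2 (AT5G01220), a sulfolipid synthase (-1.83), FER4 (AT2G40300), a ferritin (-1.67), GI (AT1G22770), an evening clock gene (-0.93), FBA5 (-2.83), AT2G03980 (-2.15), AT5G03545 (-3.27), AT2G08950 (-3.25) and AT1G08757 (-1.68). For genes with 3 counts or fewer over a group only the test is given, as edgeR adjusted p = 4.44e-07 for CSLA01, 0.000412 for FAMT, 0.0157 for PDF1.2c, 0.00388 for AT5G14650, 1.83e-05 for AT5G46960, 0.00346 for AT5G44990, 0.0124 for AT5G64790, 0.000776 for AT4G10860 and 0.0497 for AOX1D.

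The SNAP33 difference was lost with the replicate block (edgeR adjusted p = 0.0781), with DESeq2 (0.056), with upper-quartile scaling (0.0625) and without any 1 library except snap33 5 d replicate 3 and wild-type 12 d replicate 2, in a range of 0.00467 to 0.205. That of AOX1D was lost with the replicate block (edgeR adjusted p = 0.0578), with 3 other settings and without any 1 library except wild-type 5 d replicates 1 and 2 and wild-type 12 d replicate 3, in a range of 0.00837 to 1. That of PCNA1 was lost with upper-quartile scaling (edgeR adjusted p = 0.0606) and without any 1 library except snap33 5 d replicates 1 and 2, snap33 12 d replicate 3 and wild-type 12 d replicate 2, in a range of 0.00813 to 0.0984. Without wild-type 5 d replicate 1 the calls of NPR1 (edgeR adjusted p = 0.0542, range 0.00394 to 0.0542) and PDF1.2c (0.053, range 4.32e-05 to 0.053) were lost, and without wild-type 5 d replicate 2 that of CYP71A12 (0.102, range 2.58e-06 to 0.102). Without wild-type 5 d replicate 3 those of PCR1 (edgeR adjusted p = 0.106, range 1.33e-06 to 0.106), BIP3 (0.146, range 0.000686 to 0.146) and AT5G64790 (1, range 0.0002 to 1) were lost. PRP1 was lost without snap33 12 d replicate 2 (edgeR adjusted p = 0.0561) or snap33 5 d replicate 2 (0.0563), in a range of 0.00606 to 0.0563.

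More genes were called at 12 d (7826) than at 5 d (2445), and depth or a few abundant genes could give such a difference. With all libraries thinned to 1 total the ratio of the counts was still 3.18 (7443 against 2343), and without the 20 most abundant genes it was 3.2 (7819 against 2442), which argues against both. The earlier planting date that the labels give for snap33 at 12 d would bring older plants, but the phase change and flowering list, whose median rose by 2.15 with age in wild type, had a median of -0.49 in snap33 against wild type at 12 d. That argues against plants of a later stage, though not against older plants that develop slowly, so the planting date and the genotype both stay open. The hour of harvest stays open too, because the mean shift between morning and evening clock genes of 0.03 averages over TOC1 (0.89) and GI (-0.71), both called and in opposite directions, which the limit set in advance did not allow for.

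Photosynthesis genes were lower in snap33 at 12 d (median -0.51), which might come from a larger share of root or from induced genes taking up the library. The higher of the medians of the 2 root lists was -0.9, so markers of root were lower too. That goes against more root only if these genes kept their level within the root. Root hair markers were lower in snap33 at 5 d as well (median -0.93), so that cannot be assumed and more root stays open. With no scaling factors the median of all tested genes was -0.043 and that of the photosynthesis list -0.52, which argues against a dilution by induced genes. A biological effect of the genotype and the planting date stay open and were not separated.

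Regrouping the 6 libraries of a comparison into 3 and 3 gives 10 splits, too few for a share under 0.05. The real split was the 1 with as many calls at 5 d (2445), at 12 d (7826), in wild type over time (7670) and in snap33 over time (10315), and the highest other split called 0 genes in each. For the difference, 1 of 100 splits drawn from 200 called as many genes as the real one (4466), a share under 0.05. The highest other, with 4252, was 1 of the 14 other splits that kept the genotypes apart at 12 d, whereas the 85 that mixed them called at most 86, which points to the 12 d genotypes as the structure of the samples behind such counts. Since the numbers pair the samples, the fitting comparison is with all 32 splits that part the pairs at both ages, of which 2, the real one included, called as many genes, a share of 0.0625 and not under 0.05. The other, with 7050 genes, exchanged the genotypes at 12 d and so tests the sum of both effects, and the 24 that mixed the genotypes at 12 d called at most 138, so the high counts of the 7 others that keep them apart (2785 or more) go with the 12 d genotypes.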

How the results depend on the processing

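Lists under other scalings and thinned libraries were the tests chosen only after the result was seen. A fold of at least 2 left 706 genes at 5 d, 2590 at 12 d, 2084 for the difference, 2489 in wild type over time, 4283 in snap33 over time and 283 shared between the ages, as that requirement removes smaller changes by construction. An estimated correlation left 3 lists called at 5 d and 7 at 12 d. Leaving out 1 library gave 1468 to 3223 genes at 5 d and 711 to 1413 shared genes. The other total counts stayed within 1.5 times under every alternative run, but counts by direction at 5 d and shared between the ages did not. With the replicate block 1655 genes were called at 5 d, 6892 at 12 d and 3486 for the difference. Without it, as in the main fit, these counts were 2445, 7826 and 4466. No called gene or list was reversed. Of 303 called gene results DESeq2 lost 19, the replicate block 16, upper-quartile scaling 6, no filter 4, median-ratio scaling 1 and leaving out organelle genes 0. Thinning lost 6 and left 296, a fit of only the groups compared lost 6 and left 213, a stricter filter lost 2 and left 285, and leaving out 1 library lost a call 189 times and left it 3447 times. Of 44 called lists the estimated correlation lost 28, fry 4, upper-quartile scaling and the block 2 each, leaving out the 20 most abundant genes 1 and median-ratio scaling 0, and leaving out 1 library lost a call 20 times and left it 508 times. The block lost the calls of BIP2 (AT5G42020) (edgeR adjusted p = 0.0554 at 5 d, range 0.00479 to 0.171), of ICS1 at 5 d and of SNAP33 and AOX1D in the difference, and 12 calls of genes given by symbol alone (WRKY54, WAK2, MAM3, CRT2, SAR1A, IAA19 and COBL9 at 5 d, BCAT4, UPOX, MCM3, IAA3 and KIN1 at 12 d), and it changed no other call of a named gene from called to not called. Of the 53 gene results given by symbol alone 29 were lost under at least 1 alternative and 0 reversed. Depth limits genes near 0 counts, for which only bounds or counting intervals are given. The cause was not tested where none is named.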

Other observations

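Both jasmonate tests were chosen only after the result was seen. Iron genes were partly higher in snap33 at 12 d, where 4 of 9 iron deficiency and storage genes were higher (BHLH38, BHLH39, BHLH100 and BHLH101, factors induced by iron deficiency), 3 lower (the ferritins FER1, FER3 and FER4) and 2 not called, the same adjusted over the list alone (median -0.12, camera adjusted p = 0.705, with the test pointing up and the median below 0). At 5 d, 2 (FER1 and FER3) were lower, 0 higher and 7 not called, the same adjusted over the list alone (median -0.18, camera adjusted p = 0.462). BHLH38 was 5.27-fold higher (2.4, SE 0.22) and FER4 3.62-fold lower (-1.85, SE 0.19) at 12 d. Of 9 phosphate starvation genes 6 were lower at 12 d, 0 higher and 3 not called, the same adjusted over the list alone (median -1.1, camera adjusted p = 0.0667). SQD2 was among them (-1.37, SE 0.24). The list was called with the replicate block (camera adjusted p = 0.0248) and without snap33 12 d replicate 3 (0.0435), wild-type 12 d replicate 1 (0.0213) or wild-type 12 d replicate 2 (0.013), in a range of 0.013 to 0.56. Of 14 aliphatic glucosinolate genes 4 were higher at 12 d (CYP79F2, MAM3, BCAT4 and SOT17), 4 lower (MYB28, MYB29, CYP79F1 and MAM1) and 6 not called, the same adjusted over the list alone (median -0.11, camera adjusted p = 0.823). At 5 d, 1 (FMOGS-OX1) was higher, 1 (MAM3) lower and 12 not called, 3 and 1 adjusted over the list alone (median 0.24, camera adjusted p = 0.362).

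Other lists moved in few members. At 5 d the oxidative stress list had 5 of 31 higher (GSTU5, CYP81D11, ZAT12, ZAT10 and ZAT7), 1 (GSTU24) lower and 25 not called (median 0.03, or 0.04 at the bounds, camera adjusted p = 0.278). The endoplasmic reticulum list had 2 of 21 higher (BIP3 and SAR1A), 3 lower (BIP2, CRT2 and ERDJ3B) and 16 not called, 2 and 5 adjusted over the list alone (median -0.21, camera adjusted p = 0.249). BIP3 was 2.69-fold higher at 5 d (edgeR adjusted p = 0.0233), lost without snap33 5 d replicate 1 (0.0922) or 2 (0.0596) or wild-type 5 d replicate 1 (0.103) or 2 (0.0839), in a range of 0.00408 to 0.103. The SNARE list had 1 of 33 higher (VTI12), 0 lower and 32 not called (median 0.05, camera adjusted p = 0.365), with SYP121 at 0.16 (SE 0.13) and SYP122 at -0.04 (SE 0.17). Auxin response genes had 0 of 16 higher, 1 (IAA19) lower and 15 not called at 5 d, 0 and 0 adjusted over the list alone (median -0.03, camera adjusted p = 0.376), and 2 higher (GH3.3 and GH3.6), 4 lower (IAA1, IAA3, IAA17 and PIN3) and 10 not called at 12 d (median -0.01, camera adjusted p = 0.728). None of 11 wall genes and of 9 endodermis markers was called by edgeR at 5 d (medians -0.1 and -0.2, camera adjusted p = 0.365 for both). At 12 d cell division genes had 0 of 38 higher, 4 lower (TPX2, EDE1, MCM3 and CDT1A) and 34 not called, 0 and 0 adjusted over the list alone (median -0.05, camera adjusted p = 0.44). TPX2 (AT1G03780) was lost with DESeq2 (adjusted p = 0.0824) and without snap33 12 d replicate 1 (0.0769) or 3 (0.0794) or wild-type 12 d replicate 2 (0.119), in a range of 0.0106 to 0.119. EDE1 (AT2G44190) was lost without snap33 12 d replicate 1 (edgeR adjusted p = 0.0581) or 3 (0.0545), in a range of 0.00117 to 0.0581, and CDT1A (AT2G31270) with DESeq2 (adjusted p = 0.0503) and without wild-type 12 d replicate 2 (0.0923), in a range of 0.005 to 0.0923. Abscisic acid and cold genes had 6 of 20 higher, 3 lower (COR47, KIN1 and ERD10) and 11 not called (median 0.19, camera adjusted p = 0.368). Hypoxia genes had 3 of 11 higher (PGB1, SUS1 and HUP26), 1 (SUS4) lower and 7 not called (median -0.07, camera adjusted p = 0.883, with the test pointing up). Seed storage genes had 0 of 4 called at 5 d (median 0.43, camera adjusted p = 0.495) and 1 (SESA5) higher at 12 d, 2 adjusted over the list alone (median 2.61, or 1.14 at the bounds, camera adjusted p = 0.186). Phase change genes had 1 of 8 (PI) higher at 5 d and 3 lower (SPL4, SEP1 and SEP3) at 12 d (camera adjusted p = 0.96 and 0.298), and clock genes 1 of 12 (RVE1) higher and 1 (CCR2) lower at 5 d, 4 and 1 adjusted over the list alone, and 1 (TOC1) higher and 3 lower (GI, LUX and RVE1) at 12 d (camera adjusted p = 0.365 and 0.434). Fry, which does not compare a list with other genes, called the phase change list lower at 12 d (adjusted p = 0.00099, range over all alternatives 0.00099 to 0.432), the oxidative stress list higher at 5 d (0.0256, range 0.0256 to 0.613) and the seed list higher at 12 d (0.0171, range 0.0171 to 0.4). For the lists just given without a count adjusted over the list alone, it was the same.

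In wild type from 5 d to 12 d, 9 of 12 systemic resistance markers, 22 of 33 immune receptors and 13 of 21 WRKY factors rose (medians 3.71, 0.67 and 0.89, camera adjusted p = 0.000115, 2.05e-05 and 0.000122), with 0, 1 and 1 lower, and 9, 23 and 13 higher adjusted over the list alone. The markers were not called with an estimated correlation (camera adjusted p = 0.119). Of 11 hypoxia genes 9 rose and 0 fell, 10 adjusted over the list alone (median 1.14, camera adjusted p = 0.000461), and of 9 phosphate starvation genes 8 rose and 0 fell, the same adjusted over the list alone (median 2.12, camera adjusted p = 0.000115, but adjusted p = 0.215 with an estimated correlation), IPS1 from 1 to 433 counts (379-fold, interval 67.6 to 15000).

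A hypothesis is that young snap33 seedlings show jasmonate changes that wild type shows later, since the list was higher in snap33 at 5 d (median 2.07) and rose in wild type with age (2.14), and 1045 genes were higher in both (333.1 for independent lists) and 690 lower in both (172.4). Both comparisons use the wild-type 5 d libraries, and 20 simulations with no effect gave a covariance over 15235 genes of at most 0.021 against 0.29 observed (r = 0.643 observed and 0.501 simulated on average, across genes, which are not independent replicates). The simulations gave at most 1 shared call in 1 direction. With no effect few genes can be called at all, so that count cannot be set against the 1045 and 690 shared genes. The covariance argues against independent noise in the shared libraries as its whole source. Part may come from that noise, since the 3 libraries were not split between the comparisons. The simulations held no offset common to all 3 libraries, as from a shared plate or batch of seed, so such an offset stays open. Seedlings that were further developed in general might also give the resemblance, but the phase change list had a median of 0.09 at 5 d against a rise of 2.15 with age in wild type, and flavonoid genes were higher at 5 d (1.03) where they fell with age (-1.19), which argues against an advance of all groups. A partial advance stays open, as does the genotype, since abscisic acid (0.91 at 5 d and 1.94 with age), senescence (0.65 and 1.3), phosphate starvation (0.46 and 2.12) and cell division genes (-0.31 and -1.02) had medians of the same sign in both. So did salicylic acid genes (0.23 and 0.47), systemic resistance markers (1.54 and 3.71), immune receptors (0.48 and 0.67), WRKY factors (0.47 and 0.89) and camalexin genes (0.33 and 0.48). In contrast, hypoxia (-0.48 and 1.14), root hair (-0.93 and 0.35), photosynthesis (0.13 and -0.1) and endodermis genes (-0.2 and 0.49) had opposite signs. Apart from the phase change and endodermis lists, lists that camera did not call at 5 d are left out here.

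Of the 100 tested genes on each side of SNAP33 (200 in all), 29 were called at 5 d, 1.12 times the share of all tested genes (14.5% against 13%). Genes with at most 3 counts over the 6 libraries of 1 genotype and at least 5 CPM in every library of the other numbered 0.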
